A study of Homo sapiens with 5 samples.

How the data were processed

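Total RNA from 1 pool of human vastus lateralis muscle, named pool 2 of insulin-sensitive samples in the labels, was measured on 5 Affymetrix array designs, HuFL and Hu35K subA to subD. All 5 hybridisations come from the same pool, so they are technical measurements of 1 condition, and they differ in the probe sets they carry. A probe set is a group of short oligonucleotides designed against 1 transcript.

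The value tables as deposited hold 1 whole number per probe set, an intensity on a linear scale. That the values are intensities was read from the numbers themselves, since between 30.1% and 39.3% of them lie below 0, which implies that background or mismatch signal had been subtracted by the authors or their software. The software, its version, the scaling and any detection calls are not given in the sources used here, so the exact expression measure remains unknown. The trimmed means of the arrays (2% trimmed from each end) differed 5.87-fold, which mixes scale with the different genes of each design, and no scaling is stated, so intensities were not compared between arrays except for control probe sets, and all gene-level work used ranks within an array. No log was taken, because values below 0 have none.

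Gene names came from the platform annotation supplied with the tables. It gave 1 gene symbol for 5709 of 7129 HuFL probe sets, several for 321 and none for 1099. On subA, 7564 of 8934 had 1 symbol, 154 several and 1216 none; on subB, 5108 of 8924, 94 and 3722; on subC, 5755 of 8928, 126 and 3047; on subD, 5650 of 8928, 162 and 3116. Gene identifiers matched a RefSeq gene table of assembly GRCh38.p14 for 5704, 7549, 5091, 5739 and 5628 of the single-symbol probe sets of HuFL and subA to subD, and 0 symbols needed updating. That table served for names only, and no coordinates are given because the array tables name no genome build. Probe sets with several genes or none entered the percentiles but no gene. Gene-level work covered 14718 genes. Y-linked genes and XIST were left out of it. Control probe sets (59 on HuFL, 77 on each Hu35K array) were left out of everything except the comparison of controls.

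The detection threshold of an array was the smallest intensity t at which the number of values at or below -t was at most 0.05 of the number at or above t, which takes the values below 0 as noise mirrored around 0. The share of probe sets above it carries an exact binomial 95% interval for counting error. The looser threshold was 3 robust standard deviations of the mirrored noise (1.4826 times the median size of the values below 0). On simulated arrays with the noise of each real array and 200 raised probe sets, the threshold recovered 99.5% to 100.0% of probe sets set at 2 or 4 times the 99.5th percentile of the noise, and between 0% and 1.5% of those set at 1 times that percentile, so only strong signals pass. Of the calls made in simulation, 1.96% to 4.33% were false with signals at 2 times that percentile and 3.85% to 7.83% at 4 times, so the share can exceed the 0.05 set by the rule. At 1 times it was 40% on HuFL, 75% on subC and 50% on subD, of few calls. The simulated noise took the values below 0 with random signs. Symmetry around 0, which the threshold assumes, was thus built in, so these shares do not test it on the real arrays.

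The value of a gene was the mean within-array percentile of its probe sets, on the array holding most of them (ties went to HuFL, then subA to subD). A gene counted as above the threshold when at least 1 of its probe sets on any array was. Where probe sets of a named gene disagreed, the separate intensities or the lowest and highest of them are given. For each gene list the median percentile was placed among 10000 random lists of the same size drawn from the same arrays, and a list stood apart when under 2.5% of random lists reached its median on that side. This describes 1 pool and is not a test across samples. In simulation, unchanged lists stood apart in 6.5% (8 genes) and 6% (20 genes) of 200 draws, and lists shifted by 30 percentile points were recovered in 62.5% and 88.5%.

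The 23 lists were fixed before the data were examined: slow-fibre, fast-fibre and shared sarcomere genes, insulin signalling, glucose uptake and glycogen metabolism, glycolysis, oxidative phosphorylation, the tricarboxylic acid cycle with pyruvate entry, fatty acid uptake and oxidation, energy regulators, cytosolic ribosomal proteins, and markers of satellite cells, adipocytes, endothelium, smooth muscle, fibroblasts, erythroid cells, leukocytes and Schwann cells, with liver, brain, pancreas and heart as background. Another 8 lists were added afterwards and appear only among the additional observations. Genes were named by a rule fixed at the same time: the 2 genes of each list with the highest percentile, 14 genes of insulin action and fibre type whatever their signal, and the 2 highest single-gene probe sets of each array. A gene named outside this rule is said to have been chosen after its values were seen.

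Control probe sets on all 5 arrays were described by mean, standard deviation and coefficient of variation over arrays. For genes on HuFL and a Hu35K array, Spearman's rho of percentiles was set against 1000 shuffled pairings, with an interval from 1000 bootstrap samples of genes. No test between conditions was run. The alternatives tried were other thresholds, other scalings of the controls, the highest probe set of a gene, the mean over all arrays of a gene, leaving out probe sets whose name marks doubtful specificity (suffixes f, r, g, i or s), random lists from genes above the threshold only, and leaving out each array in turn. Deposited detection calls had been planned as an alternative threshold and were not used here. Leaving out the values of exactly 0 on HuFL, the looser threshold for list counts, and random lists matched on the number of probe sets per gene for the highest probe set, were chosen after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.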

Results

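The data describe 1 pool of total RNA from human vastus lateralis, a large muscle of the thigh that is a usual site of muscle biopsy. The labels call it pool 2 of insulin-sensitive samples and do not say how many people contributed to it. The same pool was measured on 5 Affymetrix oligonucleotide arrays: HuFL, which mainly holds known full-length genes, and Hu35K subA, subB, subC and subD, which hold further genes and many expressed sequence tags. All 5 arrays belong to 1 condition, so no comparison between conditions was possible and no p-value is given. The comparisons were those the design allowed, between groups of genes within the pool, between the same control probe sets on the 5 arrays, and between the probe sets of a gene on HuFL and on the Hu35K arrays. Apart from the shared controls, and 465 probe sets whose name occurs on both HuFL and subA, each probe set was measured once. Single intensities therefore have no replicate error, and the number of arrays limits the precision.

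The arrays held 42843 probe sets in all, of which 42476 remained once controls were left out. Intensities below 0 made up 30.1% of these on HuFL, 33.3% on subA, 39.3% on subB, 38.4% on subC and 34.7% on subD. They served as a measure of noise for a detection threshold, which lay at an intensity of 3457 on HuFL, 3283 on subA, 1935 on subB, 3687 on subC and 1499 on subD. Above it lay 182 of 7070 probe sets on HuFL (2.57%, exact 95% interval 2.22 to 2.97) and 100 of 8857 on subA (1.13%, 0.920 to 1.37). On subB there were 27 of 8847 (0.305%, 0.201 to 0.444), on subC 31 of 8851 (0.350%, 0.238 to 0.497) and on subD 244 of 8851 (2.76%, 2.43 to 3.12). These intervals cover counting error only, and not the uncertainty of the threshold, which on subB and subC rests on very few values far below 0. With probe sets of doubtful specificity left out, and the threshold set anew on the rest, the shares were 2.57% on HuFL, 0.807% on subA, 0.618% on subB, 0.0271% on subC (2 probe sets) and 1.39% on subD; such probe sets were 28 of the 31 above the threshold on subC and 145 of the 244 on subD. Set anew in this way, the threshold moved from 1935 to 1074 on subB and from 3687 to 4980 on subC. The fall to 2 on subC therefore mixes the probe sets left out with a higher threshold. The total of 584 was 1.37% of all probe sets, and a looser threshold of 3 robust standard deviations of the noise gave 5902. At the looser threshold the mirrored noise amounted to between 22.9% (subA) and 41.6% (subC) of the probe sets called. Probe sets below either threshold are described as not above it, not as unexpressed.

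Genes of the contractile apparatus lay near the top of their arrays, and genes of both slow and fast fibres were among them. On HuFL the highest named probe set was that of ATP2A1, the calcium pump of the sarcoplasmic reticulum in fast fibres, at an intensity of 33562, and the next was MYBPC2, the fast-fibre myosin-binding protein C, at 26099, with 5266 on subD. Of the slow-fibre genes, TNNT1, slow skeletal troponin T, read 23211 on HuFL and 13958 on subC, and TNNC1, the troponin C of slow fibres and heart, read 18507 on HuFL. The myosin heavy chains of all 3 adult limb fibre types were above the threshold: MYH2, the chain of fast oxidative fibres, at 23225 on HuFL, MYH7, the slow chain, at 16326 on HuFL, and MYH1, the fast glycolytic chain, at 6930 on subD. Because probe sets hybridise with different strength and the arrays were not put on a common scale, these intensities do not rank the chains by abundance.

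By list, 10 of 13 measured fast-fibre genes and 6 of 9 slow-fibre genes had a probe set above the threshold, where random lists from the same arrays had a mean of 0.453 and 0.242. The fast-fibre list had a median within-array percentile of 99.9, above the range of 27.9 to 73.2 that held the middle 95% of 10000 random lists. The slow-fibre list had a median percentile of 92.8 (random lists 23.5 to 78.3). Sarcomere genes shared by the fibre types had a median of 97.49 (random lists 33.1 to 70.3), with 10 of 18 above the threshold. The highest by percentile in that list were MYOZ1, a Z-disc protein that binds calcineurin, at 12641 on subA and 7953 on subB, and MB, myoglobin, the oxygen store of muscle, at 21729 on HuFL. Their place among shared genes is that of the list as fixed, and the fibre types that express them were not measured. MYL1, an alkali light chain of fast myosin, read 18137 on HuFL and 15265 on subA. Outside the lists, the highest named probe set of subC belonged to CMYA5, the sarcomere-associated protein myospryn, at 20586, with a further set at 10550 on subC, 8977 on subA and 438 on subB.

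Sequence shared among myosin heavy chains makes MYH1, MYH2 and MYH7 uncertain as separate measurements, and with probe sets of doubtful specificity left out the slow-fibre median was 58.5 and the list no longer stood apart. The HuFL table listed a probe set at 0 for 2 slow-fibre genes (MYH7 and MYL2), 1 fast-fibre gene (TPM1) and 6 shared ones (ACTA1, CKM, MYBPC1, ACTN2, TPM2 and TTN), all but MYH7 named after their values were seen; for MYL2, the slow regulatory light chain, ACTA1, skeletal actin, CKM, muscle creatine kinase, and MYBPC1, a myosin-binding protein, it was the single probe set.

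**Figure D1:**
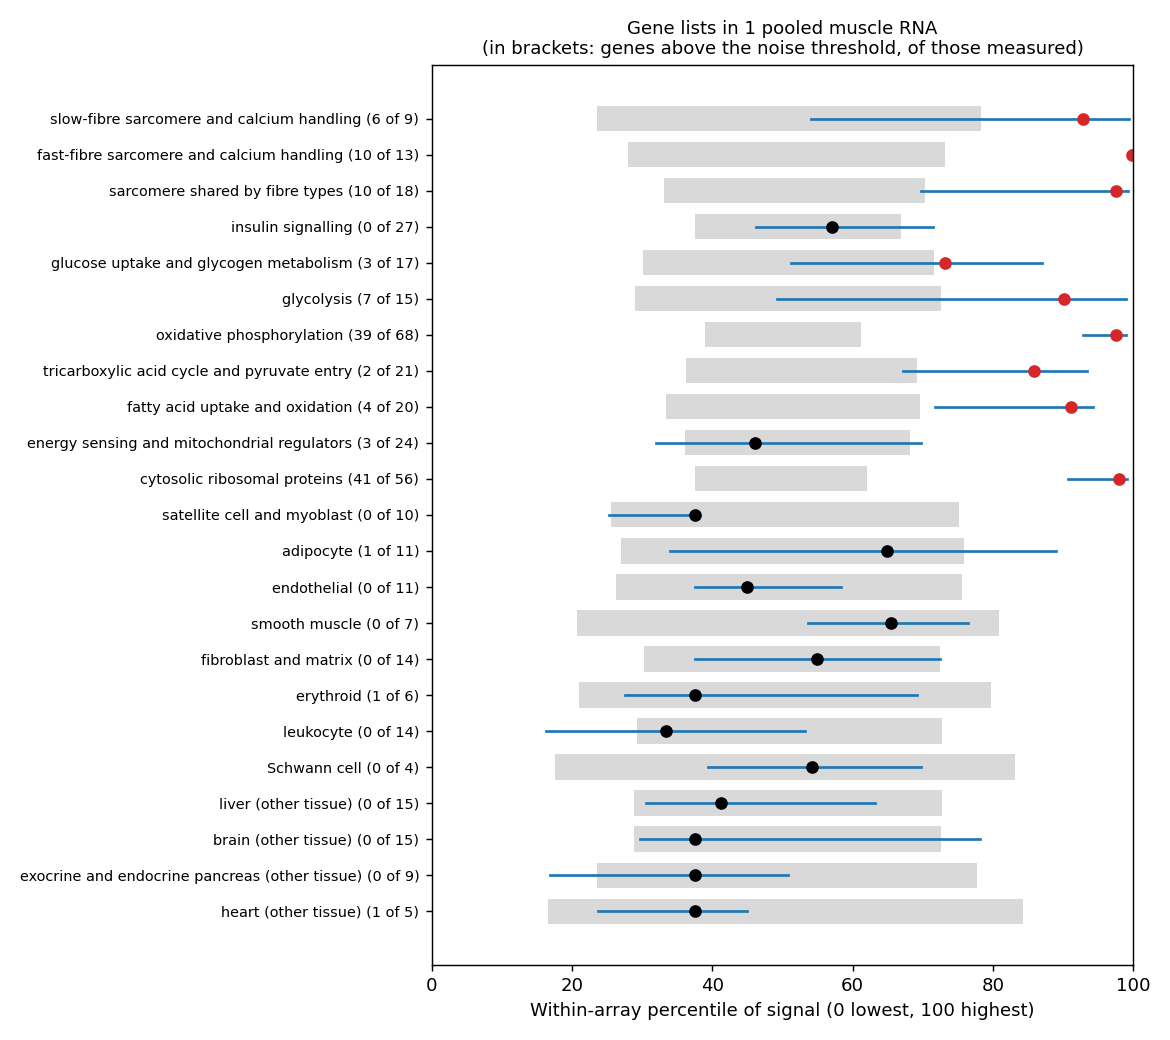
Median within-array percentile of signal (horizontal axis, 0 to 100) of the 23 gene lists fixed in advance (vertical axis); the dot is the median of a list, the blue line its interquartile range over genes, and the grey bar the middle 95% of 10000 random lists from the same arrays. Red dots mark the 9 lists that stood apart, all on the high side, from fast-fibre genes at 99.9 down to glucose uptake and glycogen metabolism at 73.2.

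Genes of mitochondrial respiration were high as a group. Of 68 measured genes of oxidative phosphorylation, 39 had a probe set above the threshold (2.12 in random lists), and their median percentile was 97.49 (random lists 38.9 to 61.1). The highest by percentile were NDUFA1, an accessory subunit of complex I, at 11703 on subA, and ATP5ME, a membrane subunit of the ATP synthase, at 8517 on subA. By complex, 13 of 29 genes of complex I (NADH dehydrogenase) were above the threshold, 0 of 3 of complex II (succinate dehydrogenase), 4 of 8 of complex III (cytochrome bc1) including cytochrome c, 10 of 13 of complex IV (cytochrome c oxidase) and 12 of 15 of complex V (ATP synthase). The genes of complex II were nonetheless in the upper part of their arrays, with a median percentile of 93.4. At the looser threshold the counts for complexes I to V were 26 of 29, 2 of 3, 7 of 8, 13 of 13 and 14 of 15. CHCHD10, a mitochondrial protein of the intermembrane space that was in no list, had the second highest named probe set of subB, at 6862.

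Fuel-oxidising pathways upstream of respiration also stood apart, with fewer members above the threshold. In the tricarboxylic acid cycle and pyruvate entry, 2 of 21 genes were above it, MDH1, the cytosolic malate dehydrogenase, at 4369 on HuFL, and MDH2, its mitochondrial counterpart, at up to 6006 on subD and as little as 403 in another set; random lists reached 2 in 14.4% of draws. The median percentile of that list was 85.8 (random lists 36.2 to 69.2), and SUCLG1, a subunit of succinyl-CoA ligase, read 2209 and 1556 on subA, below the threshold, and 58 on HuFL. Of 20 fatty acid genes 4 were above the threshold: ACADVL, the very-long-chain acyl-CoA dehydrogenase, at 7587 on HuFL, the fatty acid transporter CD36 at 4943 on HuFL (lowest set 138), and the oxidation enzymes ECI1 at 5142 on subA (the other set 1732) and HADHA at 2586 on subD (the other set 1547). Their median percentile was 91.1 (random lists 33.4 to 69.6). ECHS1, an enoyl-CoA hydratase, read 3161 on HuFL and LPL, lipoprotein lipase, 227 on HuFL, both below the threshold. PDK4, the kinase that inhibits pyruvate dehydrogenase, read 148 on HuFL, 830 on subA and 19 on subB, below the threshold on each. MDH2, CD36, ECI1 and HADHA were named after their values were seen.

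Glycolytic genes had a median percentile of 90.1 (random lists 29.0 to 72.6), and 7 of 15 were above the threshold. GAPDH, the glyceraldehyde phosphate dehydrogenase, was represented by a different probe set on each array. It read 17394 on HuFL, 15191 on subA and 11334 on subC, in probe sets whose names mark doubtful specificity. The subD set, whose name does not, read 218. ALDOA, the muscle aldolase, read 14477 on HuFL. With probe sets of doubtful specificity left out the median of the list was 70.3 and it no longer stood apart.

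Genes that carry the insulin response itself did not stand apart from random lists. None of the 27 measured insulin-signalling genes had a probe set above the threshold (mean of random lists 0.808), and their median percentile of 57.0 was inside the range of random lists, 37.5 to 66.9. At the looser threshold 10 of the 27 were called, where random lists had a mean of 6.88 and 12.1% of them had as many. INSR, the insulin receptor, read between -144 and 334 over its probe sets, with 1 of them listed at 0 on HuFL. The receptor substrates were not above the threshold either: IRS1 read between -73 and 452 over its probe sets, with 1 set of subC, at 322, above the looser threshold, and IRS2 read 239 on subA and -14 on subC. AKT1 and AKT2, kinases downstream of the receptor, read from 130 to 1143 and from 54 to 669, and TBC1D4, the AKT substrate that restrains glucose transporter traffic, read 979 on subA. When each gene was represented by its highest probe set the median of the list was 76.5 and it stood apart, but not once the random lists were also matched on the number of probe sets per gene (7.87% of them reached it), a comparison chosen after seeing the data.

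Genes of glucose uptake and glycogen metabolism stood apart by a narrow margin, with a median percentile of 73.2 (random lists 30.05 to 71.6) and 3 of 17 above the threshold (0.560 in random lists). Those 3 were PGM1, phosphoglucomutase, at 13129 on HuFL, PPP1R3C, a glycogen-targeting subunit of protein phosphatase, at 2698 on subB, and PYGM, muscle glycogen phosphorylase, at 5801 on subD and 6464 in its other set, which was named after its value was seen. SLC2A4, the insulin-responsive glucose transporter GLUT4, read 1161 and 454 on HuFL and 819 on subA, all below the threshold. GYS1, muscle glycogen synthase, read 1786 on HuFL, and HK2, the hexokinase of insulin-sensitive tissues, read -222 on HuFL, 80 on subA and -35 on subC. The position of the list was fragile. Without subB, the only array with PPP1R3C, its median was 65.8, inside the random range. The genes at the middle of the list lay at percentiles of 58.3 and 73.2, so losing any 1 higher gene gives the same shift. It also rested on the rule for genes on several arrays, since the mean over all arrays gave 64.0.

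Regulators of energy metabolism had a median percentile of 46.0, inside the random range of 36.0 to 68.2. Above the threshold were 3 of the 24, where random lists had a mean of 0.761 and 3.92% of them had as many. They were PPARGC1A, a coactivator of mitochondrial biogenesis, at 1553 on subD, and the transcription factors MEF2C at 4187 and RXRA at 1914 on subD. MEF2C and RXRA were named after their values were seen. Each had another probe set listed at 0 on HuFL, which gave MEF2C a percentile of 64.5 and RXRA 37.5. The PPARGC1A value was 1.04 times the threshold and its other probe sets read 155 on subD and 52 on subC. MEF2D, another factor of the MEF2 family, read 2054 on subA and 1647 on subB, below the threshold, and 50 and 649 on subC and subD. PPARG, the adipogenic nuclear receptor, read 710 on HuFL and 300 on subA. UCP3, an uncoupling protein of muscle mitochondria, read from 101 (HuFL) to 464 (subD).

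Cytosolic ribosomal protein genes were the other large group near the top. Of 56 measured, 41 were above the threshold (1.74 in random lists), 26 of 35 of the large subunit and 15 of 21 of the small subunit, and the median percentile was 98.0 (random lists 37.5 to 62.0). By the naming rule the leading genes were RPL23 at 11107 and RPL4 at 8081, both on subC. RPS27, RPS15 and RPS20, proteins of the small subunit, had the highest or second highest named probe sets of subA (18192), subC (16530) and subD (13904). The probe sets of these genes did not read alike: RPS27 and RPS15 were each listed at 0 on HuFL, another RPS15 set read -344 on subC, RPS20 read 565 and -104 on subC, and RPL23 read 40 on subD. Ribosomal protein genes have many processed pseudogenes, so their single intensities are uncertain.

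Markers of the other cell types that a muscle biopsy can hold did not stand apart under the main settings. Random lists had a mean between 0.0979 (Schwann cell) and 0.492 (fibroblast and matrix) genes above the threshold. A count of 0 is thus near that of random lists and does not show absence of a cell type. A count of 1 was reached by 31.3% of random lists for adipocyte and 16.7% for erythroid genes. A 0 on HuFL has the percentile 37.5, so a median of 37.5 is the percentile of those zeros and not a measured level. Satellite cell and myoblast genes had a median percentile of 37.5 (random lists 25.5 to 75.2), with 0 of 10 above either threshold, and 24.6 over 6 genes without zeros; CDH15, the cadherin of satellite cells, read 387 on HuFL, and NCAM1, the neural cell adhesion molecule of myoblasts, between -161 and 270. Adipocyte genes had a median of 64.9 (random lists 26.9 to 75.8), with 1 of 11 above the threshold, the glycerol phosphate dehydrogenase GPD1, at 3289 on subA, which is 1.002 times the threshold and is also made by muscle; ADIPOQ, adiponectin, read 1389 on HuFL and 97 on subD. The adipocyte list stood apart on the high side with the highest probe set of each gene (85.7), the mean over all arrays (73.0) or doubtful probe sets left out (78.4). Endothelial genes had a median of 45.0 (random lists 26.3 to 75.6), 0 of 11 above the threshold, with TIE1, an endothelial receptor kinase, at 416 on HuFL and FLT1, a receptor of vascular endothelial growth factor, from -16 on subB to 582 on HuFL, with a 0 on HuFL.

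Smooth muscle genes had a median of 65.4 (random lists 20.7 to 80.8), 0 of 7 above the threshold, with the actin-nucleating protein LMOD1 at 1577 on HuFL and the cytoskeletal protein SMTN at 588 on HuFL and 553 on subA. Fibroblast and matrix genes had a median of 54.9 (random lists 30.2 to 72.4), or 65.6 over 13 genes without zeros, with 0 of 14 above the threshold. The matrix proteoglycans BGN read 1842 on HuFL and -211 on subC and FMOD 1476 and 517 on HuFL. Leukocyte genes had a median of 33.3 (random lists 29.2 to 72.7), or 56.5 over 9 genes without HuFL, 0 of 14 above it, with CD3E, a chain of the T cell receptor complex, at 1087 on HuFL and LYZ, lysozyme, between -159 and 1230. Schwann cell genes had a median of 54.1 (random lists 17.6 to 83.2), 0 of 4 above it, with the glial transcription factor SOX10 at 612 on subC and the neuregulin receptor ERBB3 from 11 to 325, both on HuFL. Erythroid genes had a median of 37.5 (random lists 21.0 to 79.8), or 47.5 over 4 genes without zeros and 58.6 without subA, with 1 of 6 above the threshold, HBA2, alpha globin, at 9113 on subC, whose sequence is nearly that of HBA1; ALAS2, the erythroid enzyme of haem synthesis, read from 369 (subD) to 730 (subA), and HBB, beta globin, looked up after the values were seen, was listed at 0 on HuFL. At the looser threshold these 8 cell type lists had from 0 (satellite cell) to 6 (fibroblast and matrix, and leukocyte) genes called.

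The 4 lists of other tissues, which served as background, lay inside the random range as well under the main settings. Their random lists had a mean between 0.1675 (heart) and 0.512 (brain) genes above the threshold. For heart genes 15.5% of random lists reached 1. Liver genes had a median of 41.3 (random lists 28.8 to 72.7), 0 of 15 above the threshold, with TTR, the thyroxine carrier transthyretin, at 1448 on HuFL, 887 on subD, 122 on subA and -68 on subB, and FGG, fibrinogen gamma, at 291 on HuFL. Brain genes had a median of 37.5 (random lists 28.8 to 72.6), or 53.5 without zeros, 0 of 15 above it, with CAMK2A, a neuronal kinase, at 1446 on subA and -195 on subB and GFAP, the astrocyte filament protein, at 1366 on HuFL and 7 on subC. Pancreas genes had a median of 37.5 (random lists 23.5 to 77.8), or 19.7 without zeros, where the list stood apart on the low side, 0 of 9 above it, with the hormone somatostatin (SST) at 521 and the digestive enzyme CPB1 at 499 on HuFL. Heart genes had a median of 37.5 (random lists 16.5 to 84.3), or 35.4 without zeros, with the natriuretic peptides NPPB at 339 and -92 and NPPA at 1 on HuFL; 1 of 5 was above the threshold, MYL4, an atrial myosin light chain, at 2683 on subD, which was named after its value was seen; its 3 probe sets on HuFL were all listed at 0, and the median of the list is that 0. Genes of tissues that were not sampled thus reached intensities of 1448 (TTR) and 1366 (GFAP) on HuFL without passing the threshold.

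Over all 23 lists, 9 stood apart on the high side and 0 on the low side, where 1.15 would do so by chance on either side. Of 409 measured list members, 128 were above the threshold and 242 above the looser one.

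The human and spiked controls that all arrays carry gave the spread of deposited intensities over the 5 arrays. As the arrays were not put on a common scale, this spread mixes array scale with measurement error. It is not the error of the within-array ranks. GAPDH, measured by its middle probe set, had a mean intensity of 12870 ± 4876 (SD, n = 5 arrays), and ACTB, cytoplasmic beta actin, by its 5' probe set, 8561 ± 4096 (SD, n = 5 arrays). CreX, a phage gene spiked into the hybridisation, had 7576 ± 3445 (SD, n = 5 arrays) for its 3' probe set. Of 59 control probe sets on all 5 arrays, 9 had a mean above the highest threshold, 6 human and 3 spiked, and their median coefficient of variation was 40.8% (37.9 to 47.9). The trimmed means of the arrays ranged 5.87-fold, from 33.7 on subB to 197.8 on HuFL, but each design carries other genes: GAPDH (middle) read 16498 on HuFL and 16922 on subC, whose trimmed means were 197.8 and 57.8.

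**Figure D2:**
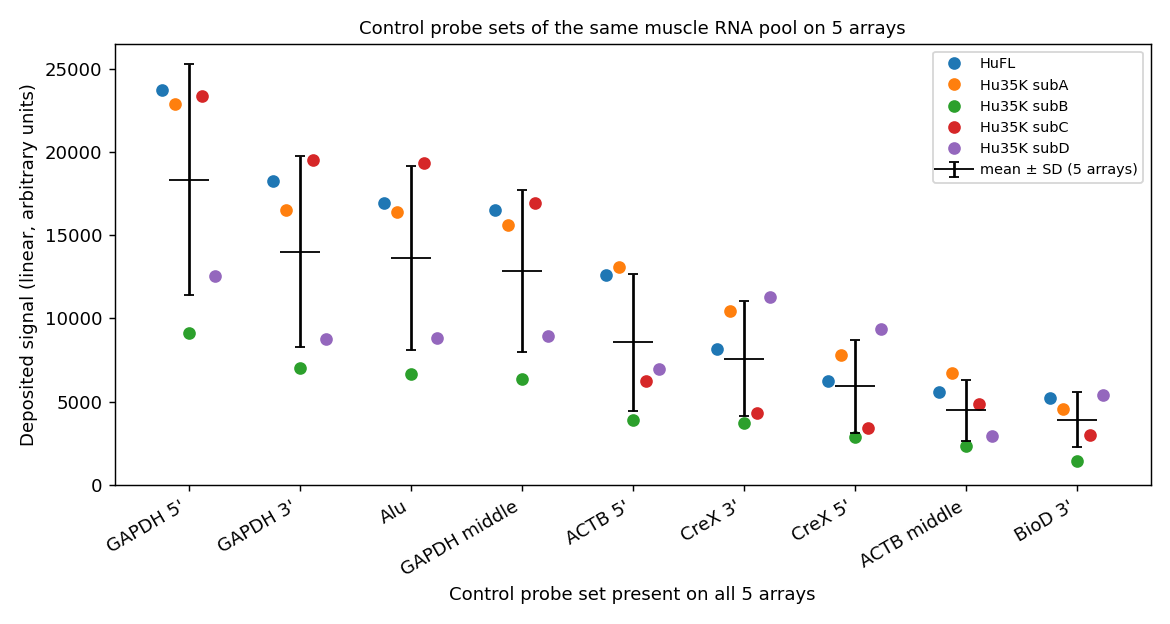
Deposited intensity (vertical axis, linear from 0) of the 9 control probe sets whose mean exceeded the highest detection threshold (horizontal axis), with 1 coloured point for each of the 5 arrays and the black marks showing mean ± SD over the arrays (n = 5). The coefficients of variation ran from 37.9% to 47.9%, and GAPDH and the spiked CreX did not move in proportion.

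Within 1 control transcript, the ratio of probe sets ranged 1.20-fold over the arrays for GAPDH and 1.11-fold for CreX, whose 5' set, at 3408, was below the threshold on subC. The ratio of the 3' to the 5' probe set was 0.759 ± 0.053 (SD, n = 5 arrays) for GAPDH. For ACTB it was 0.331 ± 0.130 (SD, n = 5 arrays), but the 3' set of ACTB was below the threshold on HuFL (2081), subB (1593) and subC (1537), so its range over the arrays is not a measured difference. The ratio of the 5' to the 3' probe set of CreX was 0.780 ± 0.034. Between transcripts, GAPDH (middle) over CreX (3') was 1.99 ± 1.18, from 0.796 on subD to 3.94 on subC, and ACTB over GAPDH, both 5', was 0.470 ± 0.127. Alu-containing transcripts over GAPDH gave 1.05 ± 0.057.

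Probe sets of the same gene on HuFL and on the Hu35K arrays, some of them with the same name on both, measured the same RNA and differed widely. Over 2854 genes represented on both, Spearman's rho of the percentiles was 0.172 (bootstrap 95% interval 0.133 to 0.208; shuffled pairings -0.037 to 0.037), a correlation across genes, which are not independent replicates. The median absolute difference was 22.6 percentile points. TNNT1, MYL1, MYBPC2 and GAPDH were among the 25 genes above the threshold on both sides, where 1.72 would be so by chance; 35 were above it on HuFL alone, 57 on Hu35K alone and 2737 on neither. HSPB1, a small heat shock protein, read 15315 on HuFL and 12747 on subD, with another subD set at 258. MDH1 read 4369 on HuFL and -2 on subB, and ACADVL 7587 on HuFL and 179 on subA. The call was the same for 96.8% of genes, and 95.1% would be the same by chance. The rho was 0.380 over the 25 genes above the threshold on both sides, and 0.0952 over 1804 genes with probe sets of doubtful specificity left out.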

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

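Of the tests in this part, the comparison of 0 with its neighbouring values and the comparison among names other than HG were chosen after the results were seen. Among 23 measures compared over the 5 arrays, 1 stood far from the rest, and chance alone puts about 1 in 20 there. It was the share of probe sets listed at exactly 0, which was 14.8% on HuFL (1047 of 7070) and between 0.203% and 0.656% on the Hu35K arrays. The zeros fell on genes of many kinds, picked out here after their values were seen: ACTA1, CKM, MYL2 and LDHA, which muscle is known to make in quantity, the red-cell gene HBB, the myogenic factor MYOD1, the macrophage marker CD163, and HP, TAT and INS of liver and pancreas.

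Rounding of signals close to 0 was argued against, because 9 probe sets read +1 and 11 read -1, a mean of 0.955% of the number at 0. Absence of the transcripts predicted a lower Hu35K percentile for genes at 0 on HuFL, and this was not seen. Their median was 2.76 points above that of other HuFL genes (bootstrap 95% interval -1.21 to 7.04, 326 and 2407 genes). The percentiles of a gene on HuFL and Hu35K were only weakly related (rho 0.172), so this comparison cannot exclude absence. Of 82 genes above the threshold on Hu35K, 13 (15.9%) were at 0 on HuFL, against 313 of 2772 others (11.3%). For those 13, a Hu35K probe set of the gene did have signal. By kind of probe set name, 0 of 496 sets with names starting HG were at 0, which allows up to 0.605%, against 14.5% of names ending in _s_at, 15.9% of plain names, 16.9% of names with other suffixes and 19.2% of names with cds or rna, at least a 31.7-fold range in all. Among plain, _s_at and cds or rna names the range was 1.32-fold (95% interval 1.02 to 1.68), below the 2-fold set for the test. A ratio of highest to lowest share cannot fall below 1, so this interval does not show a difference between these kinds. A step of the authors' processing or deposition that wrote 0 for some probe sets and spared the HG names may account for the zeros, as a hypothesis. Among list members at 0 on HuFL, probe set names starting X or Z recurred (MYL2, MYBPC1, MYOD1, MYOG and MYH8). Others started M (ACTA1 and CKM), and all these genes were picked after their values were seen. The share at 0 by first letter among names other than HG was not compared, so what picked the sets stays open. No biological explanation was tested, since the design has 1 condition.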

How the results depend on the processing

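Of 669 alternative values, 525 were counted as kept and 144 were not, and 0 changed direction. Kept means on the same side of the threshold or within the error. For the share of probe sets above the threshold it means a change within a fixed fold, which is wider than counting error. The HuFL share at a mirrored-noise ratio of 0.1, 3.45%, was counted as kept. Leaving out zeros of HuFL, the looser threshold for list counts, and matching random lists on probe sets per gene, were chosen after seeing the data. The calls of 222 list alternatives held, those of the fast-fibre and shared sarcomere lists under every alternative. The cause of the changes below was not tested. In some alternatives fewer genes or arrays entered, or the random lists came from other genes.

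The share of probe sets above the threshold, 1.37%, became 0.880% at a mirrored-noise ratio of 0.01, 2.35% at 0.1, 13.9% at 3 robust standard deviations and 19.9% above the highest Bacillus subtilis control. With doubtful probe sets left out and the threshold set anew it was 0.9997% in all, but 0.618% instead of 0.305% on subB, 0.0271% instead of 0.350% on subC and 1.39% instead of 2.76% on subD. The threshold set anew was 1074 on subB and 4980 on subC, so these shares mix the probe sets left out with a moved threshold. List members above the threshold went from 128 to 242 at 3 robust standard deviations. In simulation the main threshold recovered at most 1.5% of the weakest signals simulated.

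With probe sets of doubtful specificity left out, the slow-fibre (58.5, 7 genes) and glycolysis (70.3, 12 genes) medians no longer stood apart, and the adipocyte median did (78.4). In another alternative only genes above the threshold entered, both in the lists and in the random lists set against them. Slow-fibre (83.9), glucose and glycogen (99.3), glycolysis (99.1), oxidative phosphorylation (98.6), tricarboxylic acid cycle (93.4), fatty acid (94.8) and ribosomal (98.4) lists then no longer stood apart. Their medians were thus set against those of other genes above the threshold, not of all genes. For 10 lists there were too few such genes for a value. With the highest probe set of each gene, insulin signalling (76.5) and adipocyte (85.7) genes stood apart on the high side; with random lists also matched on probe sets per gene, adipocyte genes still did and insulin signalling did not. With the mean over all arrays, adipocyte genes stood apart at 73.0, pancreas genes on the low side at 21.1, and glucose and glycogen genes, at 64.0, did not. Without zeros of HuFL, pancreas genes stood apart on the low side (19.7).

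Leaving out arrays in turn, the glucose and glycogen median ran from 65.8 (without subB) to 85.8, losing its call at 65.8. Without HuFL the liver median was 23.5 (9 genes) and the pancreas median 4.34 (3 genes), both then low, and heart rested on 1 gene at 98.7; with other arrays left out these reached 42.5, 37.5 and 37.5. The leukocyte median moved to 56.5 without HuFL and the erythroid median to 58.6 without subA, with no change of call. The coefficient of variation of controls, 40.8%, was 56.2% after division by trimmed means, 51.3% over all controls with a mean above 0, and 30.6% (without subB) to 47.8% with arrays left out. The rho of the same gene, 0.172, was 0.380 over the 25 genes above the threshold on both sides, 0.0952 with doubtful probe sets left out, and 0.118 (without subD) to 0.196 with arrays left out. Ratios of 3' to 5' controls stayed within their spread. Of the alternatives for named genes, 207 kept their call, 58 passed the threshold only under the alternative and 3 lost it. Deposited detection calls were planned as a threshold and were not run.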

Other observations

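The tests of control ratios in this part were chosen only after the ratios were seen, and the 8 gene lists below were added after the data were examined. These lists hold genes from the 20 highest named probe sets of an array. Examples are SLN, RYR1, GAMT, ADSS1, TPT1, HSPB1, HSPB6, HSPB7 and HSPA8. Random lists were not made with the values in view, so the comparisons with them below are descriptions and give no support. Genes of excitation-contraction coupling lay high, with a median percentile of 96.6 (random lists 28.2 to 73.8) and 5 of 12 above the threshold. SLN, sarcolipin, a small inhibitor of the calcium pump, read 19033 on HuFL, RYR1, the calcium release channel, 6895 on subC (lowest set 1793), and TRDN, triadin, which anchors that channel, 6643 on subA (lowest set 41), with SRL at 4656 and JPH1 at 1723 on subD. Genes of creatine and purine energy buffering had a median of 94.6 (random lists 28.4 to 73.6), 4 of 12 above the threshold, including GAMT, the last enzyme of creatine synthesis, at 17770 on HuFL, ADSS1, the muscle adenylosuccinate synthase, at 7961 on subD and 7565 on subA, and AMPD1, muscle AMP deaminase, at 6380 on HuFL and 2139 in its other set. Translation factors had a median of 84.8 (random lists 35.8 to 67.7), 6 of 24 above it, with TPT1, the translationally controlled tumour protein, at 22393 on HuFL (lowest set 127) and EEF1A2, the elongation factor of muscle and neurons, at 10429 on HuFL. Proteasome genes had a median of 82.6 (random lists 37.5 to 68.4), 2 of 25 above it, PSMB6 at 4164 and PSMD8 at 4634 on HuFL, the other PSMD8 set reading -1258.

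The medians of the other added lists did not stand apart. Heat shock genes had a median of 66.5 (random lists 34.0 to 70.6), although 4 of 19 were above the threshold, which 0.390% of random lists reached (mean 0.633), and 11 above the looser one (mean 4.61; 0.120% reached it). The 4 were HSPB1, HSPB6, HSPB7 and the constitutive chaperone HSPA8, at 12747, 10580, 6049 and 8283 in their sets farthest above the threshold, the first 3 being small heat shock proteins of muscle. Their lowest sets read 258, -600, 557 and 208. With the zeros of HuFL left out the median of this list was 75.2 and it stood apart. Genes of HLA class I and antigen presentation had a median of 63.6 (random lists 28.04 to 73.4), 2 of 12 above the threshold (6.27% of random lists reached this), B2M at 5277 on HuFL (lowest set -65) and HLA-F at 2875 on subD, with a set at 0 on HuFL. Genes of the dystrophin complex had a median of 71.7 (random lists 27.2 to 75.5), with 0 of 10 above the threshold (mean of random lists 0.305). Above the looser one were 6, where random lists had a mean of 2.47 and 1.56% of them had as many. Cell cycle genes had a median of 36.9 (random lists 34.96 to 68.7). Of 22, 0 were above the threshold (mean of random lists 0.757) and 2 above the looser one (mean of random lists 5.19). Without the zeros of HuFL their median was 30.05 and the list stood apart on the low side.

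The controls did not keep their proportions over the arrays. GAPDH over CreX varied 4.95-fold while the ratio of the CreX probe sets varied 1.11-fold and that of GAPDH 3' over 5' 1.20-fold, so a single scale factor per array does not account for it. For a different amount of muscle RNA relative to the spikes, ACTB over GAPDH, both from that RNA, varied 2.14-fold. The test counted this against it as the whole cause. Alu-containing transcripts over GAPDH, however, varied only 1.16-fold. Saturated GAPDH sets would by themselves change ACTB over GAPDH, so the test cannot decide on the amount of RNA while saturation is open. Saturation of bright probe sets stays open: from subB to subC the GAPDH sets differed at least 2.56-fold and the dimmer ACTB sets that were above both thresholds 1.61-fold and 2.06-fold, and the ratio of the closest of these, 1.24, did not reach the 1.5 set for excluding it. No biological explanation was tested, since all arrays carry the same RNA.

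Probe sets with the same name on HuFL and subA did not read alike. Of 465 such pairs 60 were at 0 on HuFL, and over the other 405 Spearman's rho was 0.295, against 0.926 over the shared controls. Noise is a candidate explanation for part of this. Over the 16 pairs that exceeded 3 robust standard deviations on both arrays, rho was 0.768 (bootstrap 95% interval 0.395 to 0.935). Requiring a high value on both arrays leaves out pairs that disagree, so this rho cannot tell noise from other causes. Different probes behind 1 name are a further candidate explanation: of 72 pairs above that level on subA, 21 (29.2%, exact 95% interval 19.0 to 41.1) were at or below 0 on HuFL, against 0 of 22 controls, although 22.9% of all subA calls at that level are matched by mirrored noise, so the pairs do not separate these explanations. No biological explanation was tested.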
